A study of Homo sapiens with 20 samples.

How the data were processed

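The series holds 12 RNA-seq and 8 ChIP-seq samples of MDA-MB-231 cells. Per the labels, cells grew in DMEM with 10% FBS at 20% or 1% O2 for 24 h, RNA was taken with the RNeasy Mini kit and DNase treatment, RNA libraries were made with TruSeq Stranded mRNA, chromatin was prepared with SimpleChIP Enzymatic, and ChIP libraries were made with KAPA Hyper. RNA-seq has 2 libraries for each of 6 groups: parental, HIF-1/2alpha knockout and ZMYND8 knockout cells, each at 20% and 1% O2. ChIP-seq has 2 samples for each of 4 antibodies (HIF-1alpha, Bethyl A300-286A; ZMYND8, Bethyl A302-089A; H3K14ac, Abcam ab52946; H3, Novus NB500-267), all at 1% O2. Per the submitters' processing notes, reads were processed with bcl2fastq 2.17, FastQC 0.11.2, TopHat, Picard 1.127, featureCounts, edgeR, Bowtie2 2.2.3 and MACS2 2.0.10 on hg19, with no further roles given.

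The deposited RNA table is named FPKM, but its values are a normalised signal, which is how the unit was recorded: in every column the values are whole read counts divided by 1 factor per library, with no division by gene length. All values were whole after the step of each column was removed, within a tolerance of 0.05 reads. The columns sum to between 952467 and 1041688, and the recovered reads number, in units of 1e6, 24.1 to 34.3 per library. The plan assumed another unit. As the columns are scaled values and not counts, its test on log2 values was kept as the main one. For the peak lists the deposited values of each region (MACS2 fold enrichment, -log10 p and -log10 q of each peak merged into it) have the unit other, since they are lists of numbers. What the enrichment is relative to is not stated. Each antibody has 1 merged list, and the peak names show in which of the 2 samples a region was called.

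Groups, comparisons, tests, gene lists, the rule for named genes and the first set of other settings were fixed before the data were examined. Genes entered with a value of 1 or more in at least 2 of the 12 libraries, which kept 13224 of 19613. log2(value + 1) was fitted with limma 3.58.1 in R 4.3.3, 1 mean per group over all 12 libraries, with empirical Bayes moderation along a trend (9.14 residual degrees of freedom with the prior). Contrasts gave the response to hypoxia in each form of the cells, each knockout against parental cells at each oxygen level, the difference of each knockout's response from the parental one and the difference between the knockouts at 1% O2. p-values are two-sided and adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. No label pairs the replicates, so their numbers were not used as a block. With 2 libraries per group no permutation of labels within a comparison can reach 0.05. The design was tested on simulated changes in 100 genes: limma recovered 9% of 1.5-fold and 99% of 3-fold changes, with 8 calls among unchanged genes, and DESeq2 30% and 100% with 29.

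Named genes were HIF1A, EPAS1 and ZMYND8, then in each main comparison (the parental response, each knockout at 1% O2 and both differences of responses) the 8 largest changes in each direction among genes past the threshold with a mean of at least 5 in the higher group and both libraries of 1 group above both of the other (a condition not set for differences of responses), and the 4 members of each list with the smallest p. For peaks, the rule took the 10 HIF-1alpha regions with the highest score and regions within 5 kb of named genes. Of the 19 lists 18 had at least 5 tested members (344 distinct genes, 323 in the table, 296 tested). They were glycolysis and glucose uptake, other known HIF targets, collagen modification and matrix, motility, invasion and metastasis, angiogenesis factors, integrated stress and unfolded protein response, cell cycle and DNA replication, nuclear-encoded oxidative phosphorylation, interferon-stimulated genes, NF-kB and inflammatory cytokines, cholesterol synthesis and uptake, immediate early genes, mesenchymal, epithelial, luminal, fibroblast and blood cell markers, and chromatin readers and acetyltransferases. Mitochondrially encoded transcripts are absent from the table. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Changes adjusted over the list alone used the p-values of its tested members. Dates had replaced 26 gene names in the deposited file, and some genes with identical coordinates share reads.

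Of the genes called higher by hypoxia in parental cells, the overlap of those lower in each knockout was tested with Fisher's exact test across genes. Correlations between the knockouts' changes were set beside 100 simulated draws of unchanged groups against the shared parental libraries. Regions were intersected with bedtools 2.31.1 at an overlap of at least 1 bp, with 100 seeded shuffles to any position within their chromosomes for comparison. Start sites came from the coordinates of the tested genes in the RNA table, on the same build as the peaks, and a gene counted as near a region within 5 kb. Shares have 95% Wilson intervals, which cover counting error alone, since regions and genes are not independent replicates. Classes of genes near regions were compared with two-sided Fisher's exact tests over 10 tests. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

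Settings fixed beforehand were a pseudocount of 0.1, no filter, a filter at 5, quantile normalization, median-of-ratios scaling, the groups compared alone, a replicate block, moderation without trend and robust, a fold change of at least 1.5, each library left out in turn, and for peaks 0.5 reciprocal overlap, regions within 1 kb, the higher-scoring 50% of the regions and windows of 1 and 50 kb. Those added after seeing the data were edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on recovered reads, 1 factor of unwanted variation estimated within groups, a fit without the 2 libraries that stood apart, a crossed pairing of the HIF knockout libraries, regions called in both samples, regions that overlap no H3 region, regions of 1 library, strata of mean expression, 6 classes of genes and a contrast between the responses of the 2 knockouts. DESeq2 gave no adjusted p for up to 257 genes. Segments of chromosomes were found in 20-Mb windows with at least 20 genes, with 1000 permutations and bootstrap draws. The bootstrap resampled genes and not libraries, so its intervals cover the spread among genes alone. GC content was not computed, as no genome sequence on this build was at hand, and the number of genes within 500 kb on each side stood in for it.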

Results

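MDA-MB-231, a triple-negative human breast cancer cell line, was kept for 24 h at 20% or 1% O2 in 3 forms. These were parental cells, cells labelled as a knockout of HIF-1/2alpha (the oxygen-regulated subunits of the hypoxia-inducible factors, HIF) and cells labelled as a knockout of ZMYND8, a reader of acetylated histones. The series title names the question, how ZMYND8 regulates HIF activity. mRNA was sequenced in 2 libraries of each of the 6 groups. Regions bound by HIF-1alpha, ZMYND8, histone H3 acetylated at lysine 14 (H3K14ac) and histone H3 were listed from chromatin immunoprecipitation (ChIP-seq) of parental cells at 1% O2. Expression is given as normalised read counts, as deposited (mean ± SD of n = 2 libraries). Changes are log2 fold changes of 1 limma fit across all groups, with p-values adjusted over the 13224 genes tested. No label says that the 2 libraries of a group came from separate cultures, so the p-values measure the spread between them, pooled over the groups. The log2 difference between the 2 libraries of a group had an SD across genes of 0.11 and 0.12 in the parental groups, 0.24 and 0.20 in the ZMYND8 knockout and 0.31 and 0.47 in the HIF knockout at 1% and 20% O2.

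HIF1A, which encodes HIF-1alpha (hg19 chromosome 14, 62162119 to 62214977), measured 604 ± 10.1 in parental cells at 20% O2 and 188 ± 6.60 at 1% O2 (log2 change -1.68, adjusted p = 0.00016). In the HIF knockout it measured 285 ± 69.2 at 20% O2 and 462 ± 53.8 at 1% O2, lower than in parental cells at 20% O2 (-1.10, adjusted p = 0.00095) and higher at 1% O2 (1.29, adjusted p = 0.00029). In the ZMYND8 knockout it measured 496 ± 30.4 and 192 ± 10.9, and the differences from parental cells did not pass the test (-0.28, adjusted p = 0.20, and 0.03, adjusted p = 0.89). EPAS1, which encodes HIF-2alpha (chromosome 2, 46524541 to 46613842), measured 80.1 ± 3.77 and 112 ± 2.45 in parental cells at 20% and 1% O2 (0.48, adjusted p = 0.013). It was lower in the HIF knockout, at 30.5 ± 0.513 and 46.0 ± 3.83 (-1.37, adjusted p = 3.6e-05, and -1.27, adjusted p = 3.4e-05). In the ZMYND8 knockout EPAS1 measured 127 ± 5.18 at 20% O2 (0.66, adjusted p = 0.0017) and 103 ± 12.9 at 1% O2 (-0.13, adjusted p = 0.41). ZMYND8 itself (chromosome 20, 45838381 to 45985474) measured 142 ± 2.44 and 189 ± 4.35 in parental cells (0.41, adjusted p = 0.023). It measured 149 ± 7.04 and 159 ± 4.42 in cells labelled as its knockout (0.07, adjusted p = 0.63 at 20% O2, and -0.24, adjusted p = 0.11 at 1% O2). Counts over a whole gene do not check an edit, so the groups are named as labelled. The responses of EPAS1 and ZMYND8 in parental cells did not pass the test without any 1 of the 4 parental libraries (adjusted p = 0.060 to 0.11 for EPAS1 and 0.11 to 0.14 for ZMYND8). They also lay below a fold change of 1.5. The difference of ZMYND8 at 1% O2 passed without the 2 HIF knockout libraries farthest from their partners (adjusted p = 0.0080, with a range of 0.0017 to 0.24 over the alternatives that keep both replicates). In the HIF knockout ZMYND8 was also lower at 1% O2 (-0.20, adjusted p = 0.19), and by more without those 2 libraries (-0.33, adjusted p = 0.0067).

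At 1% O2 parental cells raised CA9, a carbonic anhydrase that regulates pH, from 5.05 ± 0.182 to 51.5 ± 0.625 (3.12 ± 0.12 SE, adjusted p = 4.3e-06). NDRG1, a hypoxia-responsive gene, rose from 482 ± 3.32 to 4040 ± 204 (3.06). Next by size were DUSP1, a phosphatase of MAP kinases (2.91), PTGS2, which encodes cyclooxygenase-2 (2.80), ANGPTL4, an inhibitor of lipoprotein lipase (2.74), the cytokine IL1A (2.63), IGFBP3, which binds insulin-like growth factors (2.62), and the nuclear receptor RORA (2.61). The largest decreases were in PTGES, a prostaglandin E synthase, from 78.9 ± 3.76 to 18.3 ± 0.168 (-2.05), and in the protocadherin PCDH18 (-1.98). Next were ZNF488 (-1.91), the chemerin receptor CMKLR1 (-1.85), the VIP receptor VIPR1 (-1.75), the kinase MAP2K6 (-1.75), HIF1A (-1.68) and GBP1, an interferon-induced GTPase (-1.68). For each of these 16 genes, adjusted p was 0.00025 or less and both libraries at 1% O2 lay on the same side of both at 20% O2.

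Several of the lists of genes fixed before the data were examined passed as sets in the parental response, some of them with the preset correlation alone. Of 23 genes of glycolysis and glucose uptake 16 rose and 0 fell (21 and 1 adjusted over the list alone, camera adjusted p = 1.7e-12, and adjusted p = 0.079 with an estimated correlation). Examples were ENO2 (1.65), PGK1 (1.39) and HK2 (1.54). Of 34 other known HIF targets 30 rose and 0 fell (31 and 1 adjusted over the list alone, adjusted p = 3.0e-26), with BHLHE40 at 2.09 and STC1 at 2.07. All 20 genes of the integrated stress and unfolded protein response rose (20 adjusted over the list alone, adjusted p = 9.5e-21), such as HERPUD1 (1.99), DDIT3 (2.39), HSPA5 (1.64) and ASNS (1.89). All 14 immediate early genes rose (14 adjusted over the list alone, adjusted p = 9.0e-14, and adjusted p = 0.053 with an estimated correlation), with EGR1 at 2.37 and FOS at 2.61. NF-kB and inflammatory cytokine genes rose in 15 of 21 and fell in 1 (16 and 1 adjusted over the list alone, adjusted p = 1.0e-11), with CXCL2 at 2.29 and TNFAIP3 at 1.58. Collagen modification and matrix genes rose in 8 of 16 and fell in 1 (9 and 2 adjusted over the list alone, adjusted p = 0.0078, and adjusted p = 0.22 with an estimated correlation), led by LOX (2.56). Angiogenesis factors rose in 6 of 12 and fell in 3 (7 and 4 adjusted over the list alone, adjusted p = 0.018, and adjusted p = 0.097 with an estimated correlation). VEGFA changed by 1.40 and THBS1, an inhibitor of angiogenesis, by -1.01.

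In parental cells at 1% O2 cell cycle and DNA replication genes fell in 12 of 24 and rose in 0 (16 and 0 adjusted over the list alone, adjusted p = 9.9e-09), with MCM4 at -0.89 and PCNA at -0.84. Interferon-stimulated genes fell in 9 of 23 and rose in 1 (11 and 1 adjusted over the list alone, adjusted p = 0.00093), with OAS3 at -1.10 and OAS2 at -1.04. Nuclear-encoded oxidative phosphorylation genes fell in 3 of 24 and rose in 0 (0 adjusted over the list alone, adjusted p = 0.012, and adjusted p = 0.46 with an estimated correlation), with ATP5A1 at -0.41. The other lists did not pass as sets. Of 19 genes of motility, invasion and metastasis 5 were higher and 2 lower (6 and 4 adjusted over the list alone, adjusted p = 0.15), with the collagenase MMP1 at 2.11 and the urokinase gene PLAU at -0.81. In the same order, the counts were 0 and 2 of 17 for cholesterol synthesis and uptake (0 and 2, adjusted p = 0.14). They were 3 and 0 of 9 mesenchymal markers (4 and 3, adjusted p = 0.35), and 2 and 0 of 9 epithelial markers (2 and 1, adjusted p = 0.40). Luminal markers gave 2 and 1 of 7 (2 and 2, adjusted p = 0.96; median -0.11, mean 0.05). Fibroblast markers gave 0 and 2 of 6 (0 and 3, adjusted p = 0.056) and blood cell markers 1 and 0 of 5 (1 and 0, adjusted p = 0.26). Chromatin readers and acetyltransferases gave 3 and 5 of 24 (3 and 6, adjusted p = 0.50; median 0.06, mean -0.10). Mitochondrially encoded transcripts were not tested. In all, 1311 genes rose and 1317 fell, and 4374 had an unadjusted p below 0.05. Without any 1 of the 4 parental libraries 584 to 645 rose and 444 to 499 fell, and without 1 HIF knockout library at 20% O2 2120 or 2121 fell. Without the 2 HIF knockout libraries that stood apart (replicate 1 at 1% O2 and replicate 2 at 20% O2) 2640 rose and 3110 fell. Fitted with only the groups compared 4053 rose and 4455 fell, and with 1 factor of unwanted variation 3465 and 3733. The factor was estimated from the differences between partner libraries. Fitting it lowers the spread behind the p-values, so higher counts follow in part from the fit, here and in the other comparisons.

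**Figure D1:**
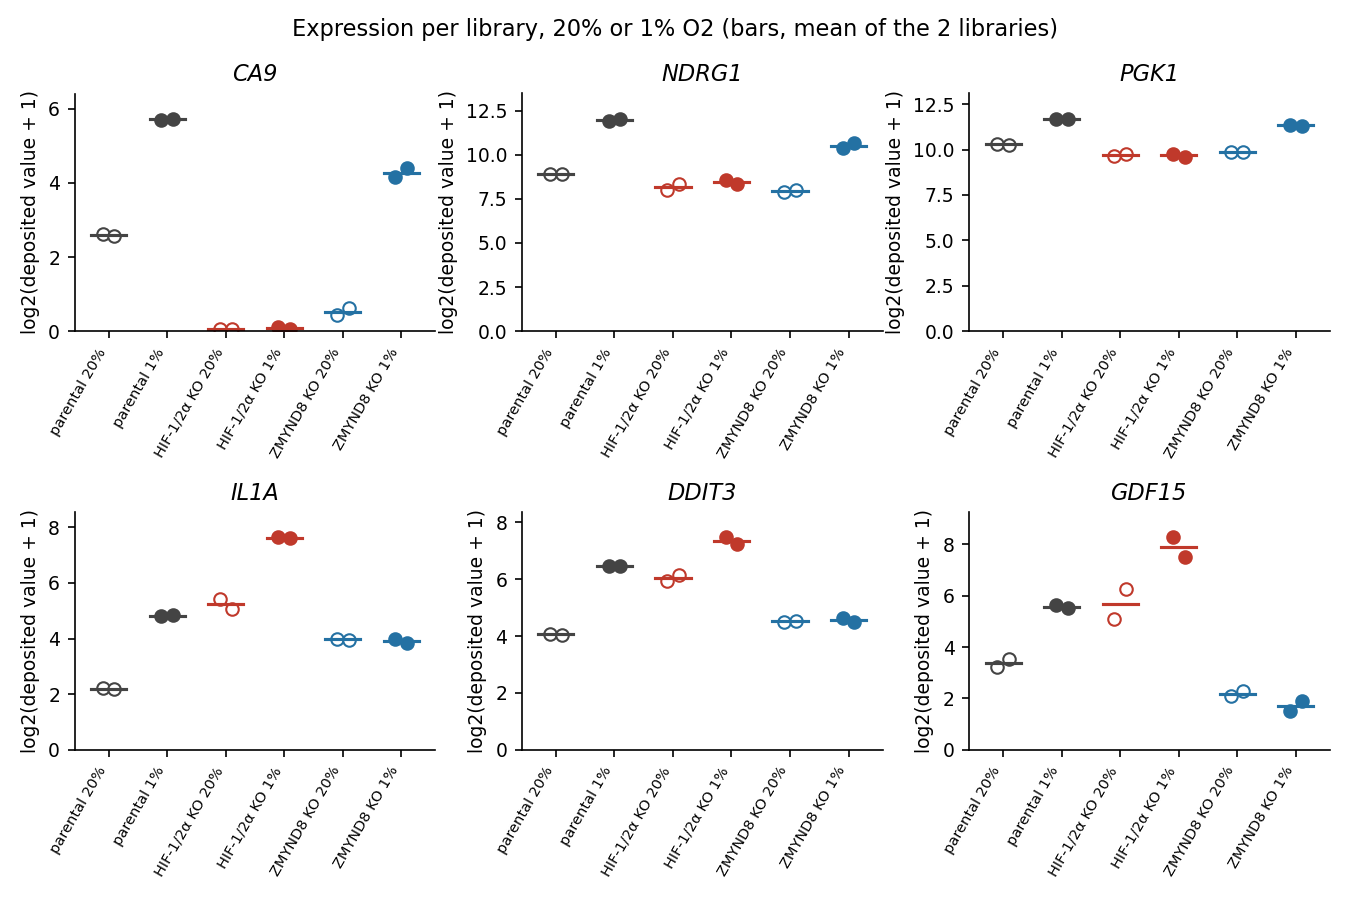
Expression of 6 genes in each of the 12 libraries as log2(deposited value + 1), by form of the cells and oxygen level, with open points at 20% O2, filled points at 1% O2 and bars at the mean of the 2 libraries. CA9, NDRG1 and PGK1 rose at 1% O2 in parental and ZMYND8 knockout cells, and IL1A and DDIT3 rose in parental and HIF knockout cells.

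In HIF knockout cells 919 genes rose and 1153 fell at 1% O2. The HIF target list did not pass as a set (8 higher and 2 lower of 34, the same counts adjusted over the list alone, adjusted p = 0.15). Glycolysis did not pass either (1 and 4 of 23, the same counts adjusted over the list alone, adjusted p = 0.19). Integrated stress genes rose in 15 of 20 (17 adjusted over the list alone, adjusted p = 2.9e-13), with HSPA5 from 4107 ± 185 to 9840 ± 336 (1.26) and ATF3 at 1.47. NF-kB and cytokine genes rose in 14 of 21 (16 adjusted over the list alone, adjusted p = 1.0e-15), with CSF2 at 2.82, IL1A at 2.39 and IL1B at 2.10. Immediate early genes rose in 11 of 14 (11 adjusted over the list alone, adjusted p = 1.2e-11, and adjusted p = 0.075 with an estimated correlation). Cholesterol synthesis and uptake genes fell in 13 of 17 (14 adjusted over the list alone, adjusted p = 1.6e-10), with HMGCS1, the synthase upstream of HMG-CoA reductase, at -1.22 and FDFT1, which encodes squalene synthase, at -1.16. Cell cycle genes fell in 7 of 24 and rose in 1 (10 and 2 adjusted over the list alone, adjusted p = 0.0050, and adjusted p = 0.075 with an estimated correlation). Matrix genes fell in 5 of 16 and rose in 2 (the same counts adjusted over the list alone, adjusted p = 0.012, and adjusted p = 0.26 with an estimated correlation), with COL4A1 at -1.17. Motility genes fell in 7 of 19 and rose in 2 (9 and 2 adjusted over the list alone, adjusted p = 0.012, and adjusted p = 0.075 with an estimated correlation), although MMP1 was higher (2.13). Luminal markers fell in 3 of 7 and rose in 1 (5 and 1 adjusted over the list alone, adjusted p = 0.032, and adjusted p = 0.12 with an estimated correlation). Angiogenesis factors had a median of 0.14 and a mean of -0.07 (adjusted p = 0.85). These lists rest on the 2 groups whose libraries differed most. Fitted with those 4 libraries alone, limma called 0 genes in either direction, while over all 12 libraries 3913 genes had an unadjusted p below 0.05 and edgeR called 887 higher and 1117 lower. Without replicate 1 at 20% O2 2215 rose and 2039 fell, and without 1 of the 1% O2 libraries 470 or 511 rose and 644 or 764 fell. A fit with 1 factor of unwanted variation gave 3360 and 3248.

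In ZMYND8 knockout cells 115 genes rose and 8 fell at 1% O2. HIF targets rose in 17 of 34 and fell in 0 (29 adjusted over the list alone, adjusted p = 6.4e-50), with CA9 from 0.446 ± 0.144 to 18.5 ± 2.43 (3.75), PPFIA4 (3.04) and NDRG1 (2.53). Glycolysis genes rose in 9 of 23 and fell in 0 (18 adjusted over the list alone, adjusted p = 6.0e-27), with PGK1 at 1.46 and LDHA at 1.30. Matrix genes rose in 4 of 16 (9 adjusted over the list alone, adjusted p = 8.0e-11), with LOX at 2.14 and P4HA1 at 1.57. Angiogenesis factors rose in 4 of 12 (6 adjusted over the list alone, adjusted p = 9.7e-06). Integrated stress genes passed as a set (adjusted p = 3.5e-05) with 1 of 20 called, ASNS at 1.08 (4 adjusted over the list alone, median 0.19). Motility genes passed with 1 of 19 called, CAV1 at 0.52 (3 adjusted over the list alone, adjusted p = 0.0026). Mesenchymal markers passed with 0 of 9 called (1 adjusted over the list alone, adjusted p = 0.025, and adjusted p = 0.093 with an estimated correlation). The median change of NF-kB and cytokine genes was -0.01 (0 of 21 called by limma, 0 adjusted over the list alone, adjusted p = 0.53). Immediate early genes had a median change of -0.01 (0 of 14 called, 1 adjusted over the list alone, adjusted p = 0.60). The number of genes at an unadjusted p below 0.05 was 1405, edgeR called 125 higher and 4 lower, and DESeq2 280 higher and 65 lower. With 1 factor of unwanted variation in the fit the balance turned, with 1196 higher and 1501 lower. The rise in calls follows in part from the fit. Without the 2 HIF knockout libraries that stood apart 568 rose and 306 fell, and without 1 ZMYND8 knockout library 45 to 69 rose and 1 or 2 fell.

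**Figure D2:**
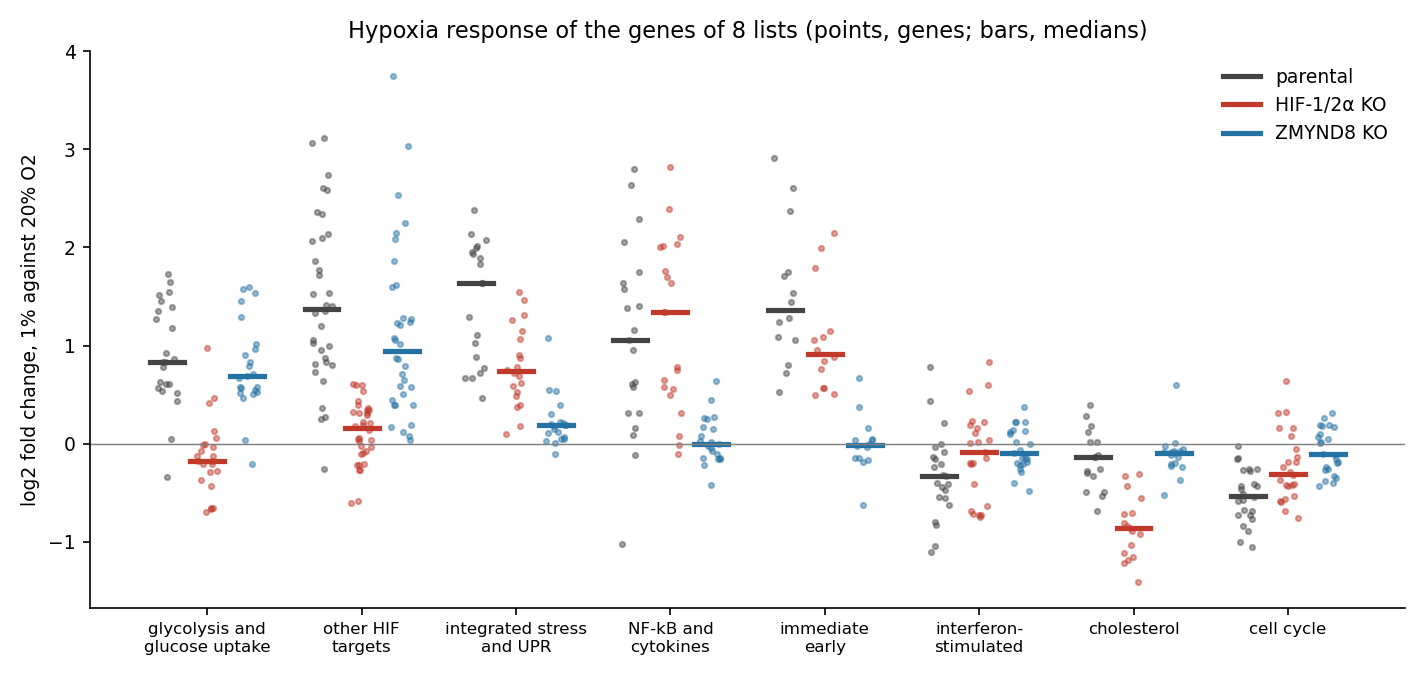
Log2 fold change at 1% against 20% O2 of each gene of 8 lists (points) with the list's median (bars) in parental, HIF knockout and ZMYND8 knockout cells. HIF targets had a median of 1.38 in parental, 0.16 in HIF knockout and 0.94 in ZMYND8 knockout cells, and NF-kB and cytokine genes of 1.06, 1.34 and -0.01.

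Against parental cells at 1% O2 the HIF knockout was lower in CA9, at 0.0573 ± 0.0350 against 51.5 ± 0.625 (-5.64, adjusted p = 2.7e-08), and PPFIA4, at 0.115 ± 0.0700 against 33.7 ± 2.14 (-4.96). EGLN3, a prolyl hydroxylase that marks HIF for degradation, measured 0.828 ± 0.0699 against 52.1 ± 0.495 (-4.86). LOC100505817 (-5.65), C10orf10 (-4.46), the aldolase ALDOC (-4.20), the elongation factor EEF1A2 (-4.15) and TSPYL5 (-4.22), which lies in a segment of chromosome 8 whose genes were lower together, were also lower. Fitted changes of genes this near 0 depend on the pseudocount. Higher were the cytokines IL24 at 217 ± 3.28 (4.18), IL1B at 387 ± 23.6 against 45.8 ± 2.87 (3.05) and IL1A at 197 ± 1.62 against 27.4 ± 0.288 (2.80). SCG5 (2.90), the complement gene C3 (2.90), ALOX5AP of leukotriene synthesis (2.84), ALDH3A1 (2.78) and the potassium channel KCNJ15 (2.76) were higher too, and adjusted p for these 16 genes was 0.00024 or less.

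Glycolysis genes were lower in 22 of 23 and higher in 0 (22 adjusted over the list alone, adjusted p = 2.2e-14, and adjusted p = 0.057 with an estimated correlation). LDHA measured 879.5 ± 50.1 against 4753 ± 69.5 (-2.43), and PFKFB4 (-3.44) lies in a segment of chromosome 3 whose genes were lower together in both knockouts. HIF targets were lower in 30 of 34 and higher in 2 (the same counts adjusted over the list alone, adjusted p = 1.3e-19). Matrix genes were lower in 14 of 16 (15 adjusted over the list alone, adjusted p = 3.3e-10), with LOX at -2.46 and P4HA1 at -2.77. Motility genes were lower in 11 of 19 and higher in 2 (the same counts adjusted over the list alone, adjusted p = 0.0021), with S100A4 at -2.35 and PLAU at 1.63. Angiogenesis factors were lower in 6 of 12 and higher in 1 (7 and 2 adjusted over the list alone, adjusted p = 0.015, and adjusted p = 0.080 with an estimated correlation). Epithelial markers were lower in 5 of 9 and higher in 1 (the same counts adjusted over the list alone, adjusted p = 0.017, and adjusted p = 0.32 with an estimated correlation). NF-kB and cytokine genes were higher in 18 of 21 and lower in 1 (the same counts adjusted over the list alone, adjusted p = 7.4e-12), with IL6 at 2.71 and CXCL3 at 2.47. Integrated stress genes were higher in 11 of 20 (13 adjusted over the list alone, adjusted p = 2.2e-05). Interferon-stimulated genes were higher in 12 of 23 and lower in 2 (13 and 2 adjusted over the list alone, adjusted p = 3.6e-05), with OASL at 2.39. In all, 1749 genes were higher and 2253 lower. Without parental replicate 1 or 2 at 1% O2 713 or 770 were higher and 1296 or 1249 lower, and without HIF knockout replicate 1, a library that stood apart, 968 were higher. With 1 factor 3999 were higher and 4090 lower, and without both libraries that stood apart 2653 were higher.

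At 20% O2 the HIF knockout had 1640 genes higher and 2108 lower than parental cells. Integrated stress genes were higher in 19 of 20 (19 adjusted over the list alone, adjusted p = 3.7e-15), with HSPA5 at 1.64 and DDIT3 at 1.97. NF-kB and cytokine genes were higher in 16 of 21 and lower in 1 (18 and 1 adjusted over the list alone, adjusted p = 6.7e-11), with IL1A at 3.05, IL1B at 2.59 and IL6 at 2.47. Interferon-stimulated genes were higher in 11 of 23 and lower in 1, MX1 at -1.17 (12 and 2 adjusted over the list alone, adjusted p = 0.0031). Cholesterol genes were higher in 7 of 17 (8 adjusted over the list alone, adjusted p = 0.00063). Immediate early genes were higher in 5 of 14 (5 higher and 1 lower adjusted over the list alone, adjusted p = 0.0031, and adjusted p = 0.44 with an estimated correlation). Cell cycle genes were lower in 15 of 24 (17 adjusted over the list alone, adjusted p = 2.9e-05), with PCNA at -0.93. HIF targets were lower in 17 of 34 and higher in 4 (20 and 4 adjusted over the list alone, adjusted p = 0.00029, and adjusted p = 0.25 with an estimated correlation). CA9 measured 0.0387 ± 0.00245 against 5.05 ± 0.182 (-2.54). Glycolysis genes were lower in 11 of 23 (11 adjusted over the list alone, adjusted p = 0.00048, and adjusted p = 0.43 with an estimated correlation). Matrix genes were lower in 8 of 16 and higher in 1 (9 and 2 adjusted over the list alone, adjusted p = 0.0050, and adjusted p = 0.25 with an estimated correlation). Mesenchymal markers had a median of 0.22 and a mean of -0.09 (adjusted p = 0.59). Fitted with the 4 libraries compared, limma called 247 genes higher and 379 lower. Without HIF knockout replicate 1 3184 were higher and 3795 lower, and without a parental library at 20% O2 642 or 665 were higher and 951 or 985 lower. With 1 factor the counts were 3164 and 3691.

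Against parental cells at 1% O2 the ZMYND8 knockout was higher in SORCS3, a sorting receptor, at 157 ± 1.51 against 0.212 ± 0.0435 (7.03, adjusted p = 2.0e-08), and in C3, at 50.9 ± 1.76 against 2.11 ± 0.0156 (4.06). The prolactin receptor PRLR was higher too, at 28.0 ± 0.104 against 1.58 ± 0.0352 (3.49). GPR110 (4.25), C15orf54 (4.15), ADTRP (4.03), the semaphorin receptor PLXNA4 (3.47) and C1orf110 (3.47) were also higher. GDF15, a stress-induced cytokine, measured 2.27 ± 0.617 against 46.8 ± 2.54 (-3.88), and ALDOC 0.337 ± 0.0591 against 23.2 ± 0.805 (-4.18). KIAA1199, which takes part in the breakdown of hyaluronan, was also lower (-4.11). LOC100505817 (-5.03), EMC10 (-4.21), EEF1A2 (-3.43) and the collagen COL6A2 (-3.42) were lower, and the calcium channel subunit CACNA2D4 was listed at 0 in both libraries against 9.86 ± 0.307. The adjusted p of these 16 genes was 6.0e-05 or less.

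Integrated stress genes were lower in 19 of 20 and higher in 0 (19 adjusted over the list alone, adjusted p = 6.6e-14), with HSPA5 at 793 ± 6.85 against 4104 ± 140 (-2.37) and HERPUD1 at -2.64. HIF targets were lower in 26 of 34 and higher in 1 (28 and 1 adjusted over the list alone, adjusted p = 3.0e-10, and adjusted p = 0.052 with an estimated correlation). Among them were BHLHE40 (-2.01), CA9 (-1.44) and EGLN3 (-1.24). Glycolysis genes were lower in 9 of 23 (9 adjusted over the list alone, adjusted p = 0.0033, and adjusted p = 0.37 with an estimated correlation), with the glucose transporter SLC2A3 at -1.65 and the hexokinase HK2 at -1.01. Cholesterol genes were lower in 13 of 17 (13 adjusted over the list alone, adjusted p = 3.1e-06). NF-kB and cytokine genes were lower in 12 of 21 and higher in 2 (14 and 2 adjusted over the list alone, adjusted p = 7.1e-05), with PTGS2 at -2.46 and CSF2 at -1.93. Immediate early genes were lower in 11 of 14 (11 adjusted over the list alone, adjusted p = 7.0e-07, and adjusted p = 0.18 with an estimated correlation). Epithelial markers were lower in 5 of 9 (5 adjusted over the list alone, adjusted p = 0.0045, and adjusted p = 0.32 with an estimated correlation), with the keratin KRT19 at -3.20. Interferon-stimulated genes were higher in 18 of 23 and lower in 2 (19 and 2 adjusted over the list alone, adjusted p = 2.9e-08), with OAS1 at 1.94. IFITM1, at -2.26, lies in a segment of chromosome 11 whose genes were lower together in this knockout. Cell cycle genes were higher in 9 of 24 (9 adjusted over the list alone, adjusted p = 0.00011), with MCM4 at 0.89. Oxidative phosphorylation genes were higher in 4 of 24 (4 adjusted over the list alone, adjusted p = 0.014, and adjusted p = 0.42 with an estimated correlation). Mesenchymal markers had a median of -0.07 and a mean of 0.34, and camera placed the set higher without passing (adjusted p = 0.38). In all, 1882 genes were higher and 2367 lower. Without 1 parental library at 1% O2 1035 or 1036 were higher and 1452 or 1342 lower, and without ZMYND8 knockout replicate 1 1084 were higher and 1430 lower. More were called with only the groups compared (3130 and 3822), with 1 factor (3830 and 4679) and without the 2 HIF knockout libraries that stood apart (3199 and 3934).

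At 20% O2 the ZMYND8 knockout had 1525 genes higher and 2105 lower than parental cells. Cholesterol genes were lower in 15 of 17 (15 adjusted over the list alone, adjusted p = 7.3e-07), with HMGCS1 at -1.56. Interferon-stimulated genes were higher in 13 of 23 and lower in 1 (14 and 2 adjusted over the list alone, adjusted p = 2.8e-05), with OASL at 2.21. HIF targets were lower in 16 of 34 and higher in 2 (17 and 2 adjusted over the list alone, adjusted p = 3.7e-05, and adjusted p = 0.24 with an estimated correlation), with CA9 at 0.446 ± 0.144 against 5.05 ± 0.182 (-2.07). Glycolysis genes were lower in 8 of 23 (8 adjusted over the list alone, adjusted p = 0.0030, and adjusted p = 0.34 with an estimated correlation). Among NF-kB and cytokine genes 7 of 21 were higher and 2 lower (7 and 3 adjusted over the list alone, adjusted p = 0.019, and adjusted p = 0.14 with an estimated correlation). IL1B changed by 1.90 and CCL2 by -1.39. Integrated stress genes were lower in 9 of 20 and higher in 3 (10 and 4 adjusted over the list alone, adjusted p = 0.034, and adjusted p = 0.20 with an estimated correlation). ASNS changed by -1.02 and PPP1R15A by 0.91. Matrix genes were lower in 7 of 16 and higher in 2, SPARC at 1.62 and TGFBI at 1.65 (8 and 2 adjusted over the list alone, adjusted p = 0.034, and adjusted p = 0.30 with an estimated correlation). Epithelial markers were lower in 5 of 9 (6 adjusted over the list alone, adjusted p = 0.0018, and adjusted p = 0.30 with an estimated correlation). Blood cell markers were higher in 3 of 5 and lower in 1 (the same counts adjusted over the list alone, adjusted p = 0.039, and adjusted p = 0.30 with an estimated correlation). These were LYZ, PTPRC, CD68, a lysosomal protein also made outside blood cells that measured 212 ± 15.6 against 94.9 ± 5.66, and CD14 at -1.36. Without 1 parental library at 20% O2 733 or 762 genes were higher and 1166 or 1168 lower, and without 1 ZMYND8 knockout library 875 or 779 were higher and 1298 or 1305 lower. Only the groups compared gave 3079 and 3584, 1 factor 3633 and 3997, and the fit without the 2 HIF knockout libraries that stood apart 2996 and 3772.

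The test of the difference between the HIF knockout's response to hypoxia and the parental one called 126 genes in the positive and 294 in the negative direction. HIF targets were negative in 18 of 34 (32 adjusted over the list alone, adjusted p = 1.2e-33), led by CA9 (-3.09), NDRG1 (-2.75), TMEM45A (-2.67), RORA (-2.56) and EGLN3 (-2.44). Glycolysis genes were negative in 10 of 23 (19 adjusted over the list alone, adjusted p = 9.6e-19), with PGK1 at -1.43. C10orf10 (-3.59), the BMP inhibitor NOG (-2.62), FAM115C (-2.53) and IGFBP3 (-2.47) were the other largest negative differences. Matrix genes were negative in 6 of 16 (12 adjusted over the list alone, adjusted p = 4.9e-10) and integrated stress genes in 5 of 20 (15 adjusted over the list alone, adjusted p = 1.2e-10). Motility genes were negative in 5 of 19 (9 negative and 1 positive adjusted over the list alone, adjusted p = 0.00015) and cholesterol genes in 2 of 17 (8 adjusted over the list alone, adjusted p = 2.3e-08). Most integrated stress and some cholesterol genes were already higher than in parental cells at 20% O2. As a set, stress genes stayed higher at 1% O2. Angiogenesis factors were negative in 5 of 12 and positive in 1, KITLG (6 and 3 adjusted over the list alone, adjusted p = 0.00061). Cell cycle genes were positive in 2 of 24 (5 adjusted over the list alone, adjusted p = 0.00045). Interferon-stimulated genes were positive in 1 of 23, CXCL10 at 0.98 (1 adjusted over the list alone, adjusted p = 0.0060). HIF1A (2.39), the pentraxin PTX3 (1.93), PTGES (1.89), the cytochrome CYP1A1 (1.68), CSF2 (1.44), SHISA2 (1.36), KITLG (1.35) and ALDH1A3 (1.32) were the largest positive differences, with adjusted p = 0.041 for KITLG and 0.0088 or less for the others.

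Some lists passed the test of the HIF knockout's response with a preset correlation alone. NF-kB genes were positive in 3 of 21 and negative in 1, ICAM1 (5 and 1 adjusted over the list alone, adjusted p = 0.021, and adjusted p = 0.064 with an estimated correlation). Immediate early genes were negative in 1 of 14 (2 adjusted over the list alone, adjusted p = 0.0018, and adjusted p = 0.27 with an estimated correlation). Mesenchymal markers were negative in 2 of 9 (3 adjusted over the list alone, adjusted p = 0.019, and adjusted p = 0.064 with an estimated correlation). Luminal markers were negative in 1 of 7 (3 adjusted over the list alone, adjusted p = 0.016, and adjusted p = 0.064 with an estimated correlation). Blood cell markers were negative as a set with 0 of 5 called (0 adjusted over the list alone, adjusted p = 0.013, and adjusted p = 0.17 with an estimated correlation). In this test 2293 genes had an unadjusted p below 0.05. In the HIF knockout CA9 and RORA lay near 0 at both oxygen levels (CA9 at 0.0573 ± 0.0350 and 0.0387 ± 0.00245). On recovered reads edgeR and DESeq2 did not call CA9 (-2.91, adjusted p = 0.31, and -2.86, adjusted p = 0.23, with a range of 1.1e-07 to 0.31 over all alternatives). They did not call RORA either (-0.67, adjusted p = 0.88, and -1.60, adjusted p = 0.77, with a range of 2.0e-06 to 0.88). Without 1 library the counts ran from 20 to 769 positive and from 82 to 885 negative, lowest without a parental library and highest without HIF knockout replicate 1 at 20% O2. KITLG was not called without 9 of the 12 libraries in turn (adjusted p = 0.067 to 0.17), nor with a pseudocount of 0.1, no filter, only the groups compared or the replicate block (adjusted p = 0.0504, 0.069, 0.13 and 0.071). SHISA2 was not called without 3 parental libraries in turn (adjusted p = 0.053 to 0.056) or with only the groups compared (adjusted p = 0.055). With 1 factor of unwanted variation the test called 1887 genes positive and 2022 negative.

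The same test for the ZMYND8 knockout called 141 genes in the positive and 168 in the negative direction. Integrated stress genes were negative in 13 of 20 (17 adjusted over the list alone, adjusted p = 1.2e-24), with DDIT3, the transcription factor CHOP, at 22.7 ± 1.63 at 1% O2 and 21.9 ± 0.201 at 20% O2 (-2.34), HSPA5 (-1.49) and PPP1R15A (-2.05). NF-kB and cytokine genes were negative in 10 of 21 and positive in 1 (15 and 1 adjusted over the list alone, adjusted p = 1.1e-15), with CXCL2 at 4.65 ± 0.476 and 5.22 ± 0.282 (-2.43) and IL1A at -2.71. IL1A measured 14.8 ± 0.288 at 20% O2 against 3.57 ± 0.0778 in parental cells, a higher level that gave part of its difference. At 1% O2 it lay below their 27.4 ± 0.288. Immediate early genes were negative in 8 of 14 (14 adjusted over the list alone, adjusted p = 4.4e-19), with FOS (-2.61), EGR1 (-2.40) and DUSP1 (-2.24). GDF15 (-2.69, adjusted p = 0.031) and RORA (-2.42) were the other largest negative differences. HIF targets were negative in 5 of 34 (6 negative and 4 positive adjusted over the list alone, adjusted p = 0.00025, and adjusted p = 0.29 with an estimated correlation), with STC1 at -0.99. Glycolysis genes did not pass (1 of 23 negative, 3 negative and 1 positive adjusted over the list alone, adjusted p = 0.65), nor did motility genes (median -0.02, adjusted p = 0.99). Cell cycle genes were positive in 5 of 24 (9 adjusted over the list alone, adjusted p = 1.8e-09), with MCM4 at 0.70. Interferon-stimulated genes were positive in 2 of 23, OAS2 at 0.98 and OAS3 at 0.89 (3 adjusted over the list alone, adjusted p = 0.00039). ZNF488 (1.85), CMKLR1 (1.72), VIPR1 (1.64, in the chromosome 3 segment), PCDH18 (1.62), the phosphodiesterase PDE7B (1.60), MAP2K6 (1.48), the metalloprotease ADAMTS15 (1.38) and CRISPLD2 (1.35) were the largest positive differences. Of these, 5 were among the 8 largest decreases in parental cells. EPAS1 also differed (-0.79, adjusted p = 0.032, but 0.055 with the replicate block).

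In that test 2016 genes had an unadjusted p below 0.05. RORA lay near 0 in the ZMYND8 knockout (0.197 ± 0.0927 and 0.0488 ± 0.0283). Neither edgeR nor DESeq2 called it on recovered reads (-1.93, adjusted p = 0.55, and -1.84, adjusted p = 0.46, with a range of 4.8e-06 to 0.55 over all alternatives). Without 1 library the counts ran from 18 to 391 positive and from 44 to 419 negative, lowest without a parental library and highest without a HIF knockout library at 20% O2. EPAS1, GDF15 and MAP2K6 lost their calls without 7, 8 and 5 of the 12 libraries in turn (adjusted p = 0.11 to 0.17, 0.072 to 0.16 and 0.059 to 0.066). ZNF488, ADAMTS15 and CRISPLD2 lost theirs without 6, 5 and 4 (adjusted p = 0.051 to 0.068, 0.051 to 0.061 and 0.051 to 0.056), and MAP2K6 also with a pseudocount of 0.1 (adjusted p = 0.051). Without the 2 HIF knockout libraries that stood apart 977 genes were positive and 868 negative, with only the groups compared 984 and 859, and with 1 factor 1797 and 1995.

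Compared directly at 1% O2, the ZMYND8 knockout had 2627 genes higher and 2547 lower than the HIF knockout. HIF targets were higher in 22 of 34 and lower in 5 (22 and 6 adjusted over the list alone, adjusted p = 6.6e-07, and adjusted p = 0.13 with an estimated correlation). CA9 measured 18.5 ± 2.43 against 0.0573 ± 0.0350, and PPFIA4 differed by 4.12 and EGLN3 by 3.62. Glycolysis genes were higher in 15 of 23 (16 and 1 lower adjusted over the list alone, adjusted p = 6.5e-08, and adjusted p = 0.14 with an estimated correlation). Matrix genes were higher in 12 of 16 (13 adjusted over the list alone, adjusted p = 1.8e-06, and adjusted p = 0.065 with an estimated correlation). Cell cycle genes were higher in 14 of 24 and lower in 1 (16 and 1 adjusted over the list alone, adjusted p = 2.4e-05). Integrated stress genes were lower in 19 of 20 (19 adjusted over the list alone, adjusted p = 1.1e-15), with HSPA5 at 793 ± 6.85 against 9840 ± 336 (-3.63). NF-kB and cytokine genes were lower in 19 of 21 and higher in 2 (the same counts adjusted over the list alone, adjusted p = 1.4e-11), with IL6 at 7.32 ± 0.547 against 139 ± 2.63 (-4.07). Cholesterol genes were lower in 11 of 17 (13 lower and 1 higher adjusted over the list alone, adjusted p = 0.00069). Immediate early genes were lower in 12 of 14 (12 adjusted over the list alone, adjusted p = 6.6e-07, and adjusted p = 0.14 with an estimated correlation). Fibroblast markers had a median of -0.15 and a mean of 0.11 (adjusted p = 0.97). Without ZMYND8 knockout replicate 1 1586 genes were lower, and with 1 factor 4262 were higher and 4649 lower.

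Of the 1311 genes that hypoxia raised in parental cells, 422 were lower in the HIF knockout at 1% O2, 766 in the ZMYND8 knockout, 284 in both and 407 in neither. Independent calls would give 247 in both (odds ratio 1.74, Fisher's exact test across genes, two-sided p = 6.7e-06, where genes are not independent replicates). The knockouts share the parental libraries, which also define the raised genes. What this adds to the 284 was not measured, since unchanged groups give no calls. Over these genes the covariance of the 2 knockouts' changes was 0.165, against 0.0175 on average in 100 simulated unchanged draws with shared parental libraries. Sharing alone gave a correlation of 0.53, so the observed 0.24 cannot judge likeness. The median response of these genes was 0.67 in parental, 0.32 in HIF knockout and 0.19 in ZMYND8 knockout cells. Of these genes 500 also rose in the HIF knockout and 107 in the ZMYND8 knockout. Outside 3 chromosome segments whose genes were lower together 269 of 1265 were lower in both knockouts. Without the 38 windows of 20 Mb with a median below -0.2 in a knockout as well, 213 of 1082 were. Without 1 parental library the overlap was 119 to 161, and without 1 HIF knockout library at 20% O2 431 or 432. It was 527 without the 2 libraries that stood apart and 839 with 1 factor.

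HIF-1alpha ChIP-seq listed 2755 regions, ZMYND8 31959, H3K14ac 101276 and H3 254, of which peaks were called in both samples in 52.6%, 41.9%, 59.4% and 71.7%. Of the HIF-1alpha regions 82.2% overlapped a ZMYND8 region (2265 regions, 95% Wilson interval 80.7 to 83.6%), against a mean of 0.826% when regions were shuffled within their chromosomes. H3K14ac regions overlapped 57.0% of the HIF-1alpha regions (55.1 to 58.8%, shuffled 2.72%) and 58.4% of the ZMYND8 regions (57.9 to 59.0%, shuffled 2.64%). Of the HIF-1alpha regions 1268 overlapped both, 997 ZMYND8 alone, 302 H3K14ac alone and 188 neither. H3 regions, the background measured the same way, overlapped 7.91% of the HIF-1alpha regions (7.0 to 9.0%, shuffled 0.0882%) and 0.723% of the ZMYND8 regions (0.643 to 1.32% from regions of 1 library). With 254 regions in the H3 list against 31959, these shares cannot be set directly against those with ZMYND8. HIF-1alpha overlaps were 99.6 times the shuffled mean with ZMYND8 and 89.7 times with H3. Shuffles could land anywhere and H3, a background, passed them nearly as far, so they cannot show specific co-binding. In turn, 87.8% of the H3 regions overlapped a HIF-1alpha region and 93.3% a ZMYND8 region. Among the 10 HIF-1alpha regions with the highest score 5 overlapped an H3 region and had no start of a tested gene nearer than 331204 bp. All 10 overlapped ZMYND8 and H3K14ac regions, and over the whole list 98.2% of HIF-1alpha regions on an H3 region overlapped ZMYND8, against 80.8% of the others. The other 5 of the 10 lay on chromosome 3 at 48594511 to 48594985, 284 bp upstream of PFKFB4, and on chromosome 19 at 34850010 to 34850564, 5081 bp from the start of GPI. They also lay on chromosome 12 at 8123203 to 8123644, 34311 bp from SLC2A3, on chromosome 16 at 30076566 to 30077095 within ALDOA and the annotated spans of BOLA2, BOLA2B and LOC440354, 10289 bp from the start of PPP4C, and on chromosome 15 at 93352233 to 93352673. With 0.5 reciprocal overlap HIF-1alpha regions met ZMYND8 in 49.2% and H3K14ac in 9.66%, and ZMYND8 regions met H3K14ac in 4.80%. Within 1 kb each share was higher than at 1 bp.

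**Figure D3:**
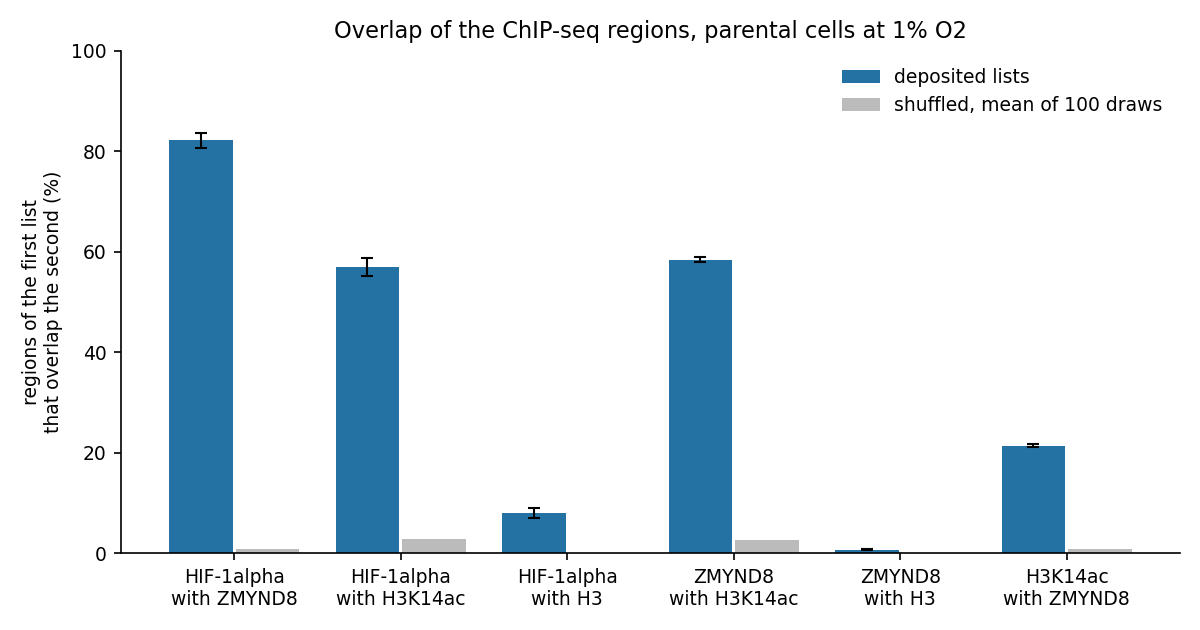
Share of the regions of 1 ChIP-seq list that overlap a region of another by at least 1 bp, in percent with 95% Wilson intervals, for 6 pairs of lists (blue) and the mean of 100 shuffled draws (grey). HIF-1alpha regions overlapped ZMYND8 regions in 82.2% and H3 regions in 7.91%, from lists of 31959 and 254 regions, so the 2 shares are not directly comparable.

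HIF-1alpha regions lay within 5 kb of the transcription start of 138 of the 422 genes that hypoxia raised and the HIF knockout lowered, 32.7% (95% Wilson interval 28.4 to 37.3%), against 7.23% of the other tested genes (odds ratio 6.24, adjusted p = 3.7e-49). Fisher's exact tests were two-sided and adjusted over 10 such tests, of which 6 were added after seeing the data. For the 766 raised genes that the ZMYND8 knockout lowered the share was 18.4% against 7.40% (2.82, adjusted p = 6.4e-21). Most other tested genes were not raised, so this test cannot tell lowering by the ZMYND8 knockout from the rise itself. For raised genes that the HIF knockout did not lower the share was 12.8% against 7.69% (1.76, adjusted p = 9.4e-07) and for genes that hypoxia lowered 3.34% against 8.56% (0.369, adjusted p = 1.1e-12). ZMYND8 regions lay near 58.5% of the first class against 57.2% (1.05, adjusted p = 0.62) and near 58.4% of the second against 57.2% (1.05, adjusted p = 0.61). They lay near 61.2% of the third against 57.0% (1.19, adjusted p = 0.022, but 0.97 with a window of 1 kb), and near 50.7% of the genes that hypoxia lowered against 58.0% (0.745, adjusted p = 1.0e-06). Within the 422 genes, those that the ZMYND8 knockout also lowered had a ZMYND8 region in 54.2% and the others in 67.4% (0.573, adjusted p = 0.019; 1.036 with a window of 50 kb, 0.90 with 1 kb, 0.76 for the higher-scoring 50% and 0.77 for regions called in both samples, none of them past the threshold), and a HIF-1alpha region in 29.9% and 38.4% (0.685, adjusted p = 0.12). By list, a HIF-1alpha region lay near 16 of 23 glycolysis genes, 25 of 34 HIF targets, 1 of 20 integrated stress genes, 2 of 21 NF-kB genes and 2 of 14 immediate early genes. A ZMYND8 region lay near 18, 25, 16, 14 and 12 of them. A HIF-1alpha region spanned the start of CA9 (chromosome 9, 35673783 to 35674036, with no ZMYND8 region within 5 kb) and of BNIP3 (chromosome 10, 133795237 to 133795765, with a ZMYND8 region over it). With windows of 1 or 50 kb the first odds ratio for ZMYND8 regions was 0.68 and 0.91, and with the higher-scoring 50% of the regions 0.96. The second was below 1 at 1 kb, but above 1 and past the threshold at 50 kb and for regions called in both samples.

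**Figure D4:**
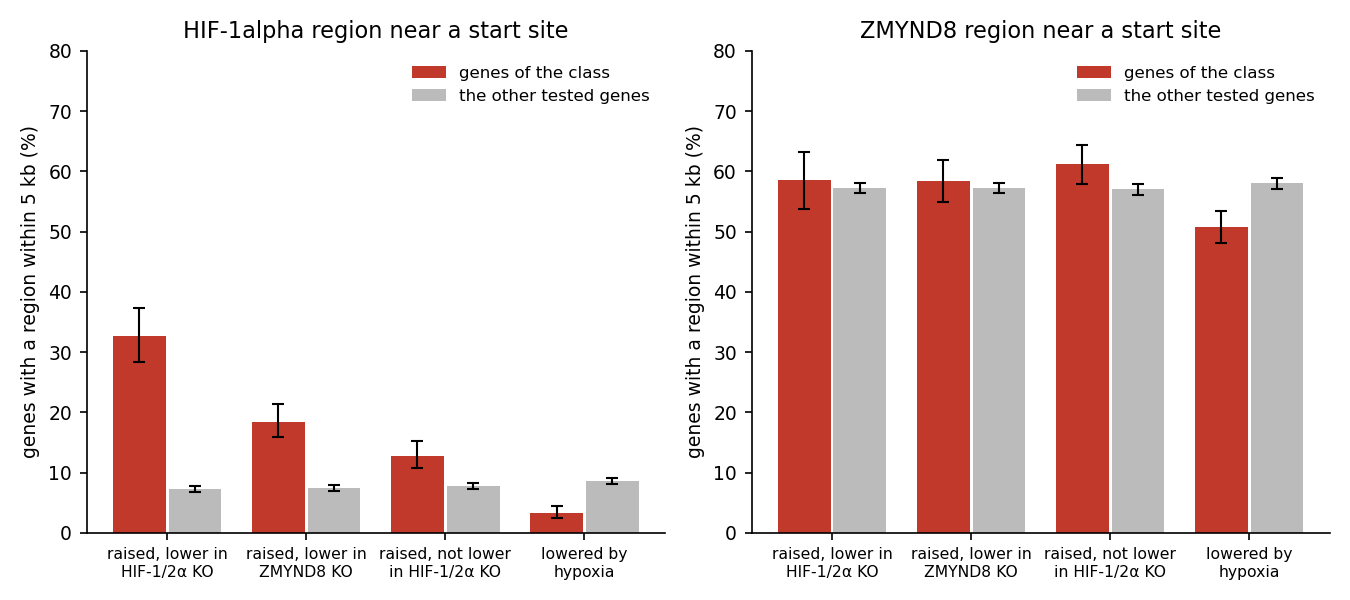
Share of genes with a HIF-1alpha region (left) or a ZMYND8 region (right) within 5 kb of the transcription start, in percent with 95% Wilson intervals, for 4 classes of genes and the other tested genes. The genes raised by hypoxia and lower in the HIF knockout had a HIF-1alpha region in 32.7% and the other tested genes in 7.23%, and a ZMYND8 region in 58.5% and 57.2%.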

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

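The tests for a chance arrangement, the library factor on the segments, the dose of the segments, gene density, exchanged labels, admixture and single cultures were chosen only after the result was seen, as were the contrast of the 2 knockouts' responses and the fits with the factor or without the libraries that stood apart, whereas the tests of the factor on the stress lists and of their level at 20% O2 were chosen before. After first versions had been run and seen, 4 tests were reworded. The factor test on the segments went from 1 segment and knockout to all 10 medians, the dose test from the share of genes lower at both oxygen levels (at least 80.3%, against 37.9% of the other genes for the ZMYND8 knockout) to the lower and upper 50% by expression, the admixture test from CA9 alone to all genes silent in the partner library, and the label test from genes picked partly by the tested libraries to genes picked by the parental libraries alone. A pair of tested explanations was dropped. A response of the segments to oxygen as the whole cause is argued against by small medians in the parental response. These were -0.07 on chromosome 3 (interval -0.12 to -0.02), -0.04 on chromosome 8 and 0.03 on chromosome 11. ZMYND8 knockout cultures without any hypoxia are argued against by a median response of HIF targets of 0.94 (interval 0.62 to 1.24). That median cannot tell a weaker hypoxia of these cultures from an effect of the knockout.

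The test of the difference from the parental response to hypoxia called 126 genes positive and 294 negative in the HIF knockout. In the ZMYND8 knockout it called 141 and 168. In the HIF knockout the median difference was -1.06 for glycolysis, -1.13 for HIF targets, -0.91 for matrix genes, -0.46 for motility, -0.50 for angiogenesis, -0.64 for integrated stress, 0.27 for cell cycle, 0.31 for interferon-stimulated, 0.19 for NF-kB, -0.69 for cholesterol, -0.44 for immediate early genes, -0.0925 for mesenchymal markers, -0.19 for luminal and -0.37 for blood cell markers. Of these, integrated stress and cholesterol genes were already higher without hypoxia. NF-kB, immediate early genes and the mesenchymal, luminal and blood cell markers did not pass with an estimated correlation. In the ZMYND8 knockout it was -0.35 for HIF targets, -1.18 for integrated stress, 0.47 for cell cycle, 0.26 for interferon-stimulated, -0.99 for NF-kB and -1.37 for immediate early genes, of which HIF targets did not pass with an estimated correlation (adjusted p = 0.29). Single genes that differed in the HIF knockout were HIF1A (2.39), PTX3 (1.93), PTGES (1.89), CYP1A1 (1.68), CSF2 (1.44), SHISA2 (1.36), KITLG (1.35), ALDH1A3 (1.32), C10orf10 (-3.59), CA9 (-3.09), NDRG1 (-2.75), TMEM45A (-2.67), NOG (-2.62), RORA (-2.56), FAM115C (-2.53) and IGFBP3 (-2.47). Neither edgeR nor DESeq2 called CA9 (adjusted p = 0.31 and 0.23) or RORA (-0.67 and -1.60, adjusted p = 0.88 and 0.77), KITLG lost its call without 9 of the 12 libraries in turn and SHISA2 without 3. In the ZMYND8 knockout they were ZNF488 (1.85), CMKLR1 (1.72), VIPR1 (1.64), PCDH18 (1.62), PDE7B (1.60), MAP2K6 (1.48), ADAMTS15 (1.38), CRISPLD2 (1.35), IL1A (-2.71), GDF15 (-2.69), FOS (-2.61), CXCL2 (-2.43), RORA (-2.42), EGR1 (-2.40), DDIT3 (-2.34) and DUSP1 (-2.24). Neither edgeR nor DESeq2 called RORA (adjusted p = 0.55 and 0.46), and GDF15, ZNF488, MAP2K6, ADAMTS15 and CRISPLD2 lost their calls without 8, 6, 5, 5 and 4 of the 12 libraries in turn.

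The 55 genes of the integrated stress, NF-kB and immediate early lists rose at 1% O2 by a median of 1.29 in parental and 0.84 in HIF knockout cells and changed by 0.04 in ZMYND8 knockout cells. The responses of the 2 knockouts differed by a median of -0.75 (95% bootstrap interval over genes, not libraries, -1.11 to -0.67). In the contrast of their responses 13 of 21 NF-kB, 7 of 20 integrated stress and 8 of 14 immediate early genes were called. A bias of libraries along the within-group factor as the whole cause is argued against by the median difference of the ZMYND8 knockout's response, which was -1.27 without and -1.15 with the factor in the fit. A level at 20% O2 already as high as in parental cells at 1% O2 is argued against, for the 55 genes as a set, by a median of -1.12 between those groups (upper bound over genes -0.86). That median does not test a smaller rise at 20% O2 in single genes, such as that of IL1A. A state of single cultures other than oxygen (medium, density, time of harvest) cannot be told apart from the knockout, since 0 label fields tie a library to a culture, dish, passage or batch. A dependence of this response on ZMYND8 remains a hypothesis beside it, and nothing here separates a direct role at these genes from an indirect one.

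Genes of 3 chromosome segments were lower together in knockout cells: chromosome 3 from 40 to 80 Mb (223 genes, medians -0.46 to -0.51 in both knockouts at both oxygen levels), chromosome 8 from 80 to 100 Mb (61 genes, -0.40 to -0.51) and chromosome 11 from 0 to 40 Mb in the ZMYND8 knockout (204 genes, -0.54 and -0.44, against 0.04 and 0.04 in the HIF knockout). The 3 were picked from windows of 20 Mb after their medians were seen, and others moved too. Relative to all genes, the medians at 1% and 20% O2 were -0.63 and -0.73 in the HIF knockout and -0.12 and -0.18 in the ZMYND8 knockout on chromosome 8 from 100 to 120 Mb, and -0.62 and -0.32, and -0.17 and -0.26, on chromosome 3 from 80 to 100 Mb. They were -0.27 to -0.40 in both knockouts on chromosomes 17 and 18 from 20 to 40 Mb, and 0.33 to 0.54 on chromosome X from 140 to 160 Mb. A chance arrangement over all 154 windows is argued against by the SD of their medians in the ZMYND8 knockout at 20% O2. This SD was 0.170, against at most 0.0768 in 1000 random placements. The parental response to hypoxia also lay above its random placements, but by little (0.0690 against at most 0.0667). The SD was taken over all windows, so it does not test the 3 segments picked from them. The library factor as the whole cause is argued against by all 10 medians keeping more than 50% of their size with the factor in the fit, narrowly for chromosome 8 in the HIF knockout at 20% O2, where -0.51 became -0.26. A lower dose of the 3 segments in the knockout lines may account for the pattern there (the other windows were not tested for it). The weakest median among the genes of lower and of higher expression was -0.31 and the strongest -0.61. These medians cannot decide for dose, because the segments were picked for low medians in the same libraries. No DNA was measured, so silencing over a region stays open beside it, and the shared segments on chromosomes 3 and 8 leave open whether the lines differ from the parental cells in more than the edit.

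In the HIF knockout, replicate 1 at 1% O2 and replicate 2 at 20% O2 stood apart from their partners, with 1 axis taking 79.2% of the variance within groups. Exchanged oxygen labels are argued against by the score of the genes called in a fit of the 4 parental libraries alone, on which both libraries labelled 1% O2 lay above both labelled 20% O2 by at least 0.290, with partners up to 0.160 apart. An admixture of parental cells is argued against by genes silent in the partner library, whose median was 1.28% of the parental mean in 1 library (3 genes) and 0.991% in the other (8 genes). A library bias along gene density may account for the difference, as the rank correlation across genes of the difference between partners with gene density was 0.489 in size at 1% O2 and 0.529 at 20% O2. Genes are not independent replicates, the ZMYND8 knockout showed the same trend (-0.24 and -0.48), and a difference between cultures that follows gene density stays open.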

How the results depend on the processing

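The fits with edgeR, DESeq2, 1 factor or without the 2 libraries that stood apart, the crossed pairing, and for regions those called in both samples, those without an H3 region and the expression strata were chosen only after the result was seen. Over the alternatives other than leaving out 1 library, these later fits included, 182 counts of genes stayed within 1.5 times their value, 49 rose above and 31 fell below that, and for named genes 1185 of 1209 values kept their direction and side of the threshold. Without 1 library 137 counts stayed, 18 rose and 85 fell, and 1059 of 1116 named values were kept. Except where the setting itself is given as the reason, the cause was not tested. Counts are given as higher and lower. At the depth of the libraries (24.1 to 34.3, in units of 1e6 reads) and 2 libraries, limma recovered 9% and DESeq2 30% of 1.5-fold changes simulated in 100 genes. In the parental response, with more genes called, some changes below 1.5-fold were called too (EPAS1 at 0.48).

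With a pseudocount of 0.1 the ZMYND8 knockout's response had 4 lower and the HIF knockout's difference of responses 82 higher, and with median-of-ratios scaling the ZMYND8 knockout's response had 4 lower. With only the groups compared the counts were 4053 and 4455 for the parental response, 0 and 0 for that of the HIF knockout (a fit of 4 libraries), 1 lower for that of the ZMYND8 knockout, 247 and 379 for the HIF knockout at 20% O2, 3130 and 3822 for the ZMYND8 knockout at 1% and 3079 and 3584 at 20% O2, and 23 and 94, and 984 and 859, for the differences of responses. With the replicate block they were 3 lower for the ZMYND8 knockout's response, 58 higher for the HIF knockout's difference and 93 and 111 for that of the ZMYND8 knockout. A crossed pairing of the HIF knockout libraries gave 2366 and 2419 for its response, against 38 and 71 paired as numbered and 0 and 0 unpaired. With a fold change of at least 1.5, which asks more of each gene, they were 823 and 566, 440 and 683, and 5 lower for the 3 responses, 817 and 1429, and 913 and 1175 for the HIF knockout at 1% and 20% O2, 943 and 1528, and 857 and 1318 for the ZMYND8 knockout, 1631 and 1628 between knockouts, and 147 for the overlap. edgeR gave 4 lower for the ZMYND8 knockout's response and 69 higher for the HIF knockout's difference, and DESeq2 280 and 65 for that response, and 273 and 580, and 371 and 351 for the differences. With 1 factor, which takes up spread between partner libraries and so raises counts in part by itself, the counts were 3465 and 3733, 3360 and 3248, and 1196 and 1501 for the responses, 3999 and 4090, and 3164 and 3691 for the HIF knockout, 3830 and 4679, and 3633 and 3997 for the ZMYND8 knockout, 1887 and 2022, and 1797 and 1995 for the differences, 4262 and 4649 between knockouts, and 839 for the overlap. Without the 2 libraries that stood apart, which also removes their spread from the pool, they were 2640 and 3110, 984 and 1249, and 568 and 306, then 2653 and 2885, and 2044 and 2618, then 3199 and 3934, and 2996 and 3772, then 383 and 647, and 977 and 868, then 3213 and 3527, and 527. Lists called with an estimated correlation numbered 5 of 10 for the parental response, 3 of 8 and 6 of 7 for those of the HIF and ZMYND8 knockouts, 6 of 9 and 5 of 9 for the HIF knockout at 1% and 20% O2, 5 of 10 and 2 of 9 for the ZMYND8 knockout, 9 of 14 and 5 of 6 for the differences and 4 of 8 between knockouts. With fry they numbered 14 for the ZMYND8 knockout at 20% O2 and 14 between knockouts.

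Without 1 library in turn (the lone partner is assumed to vary like the other groups) the counts were 584 to 1926 and 444 to 2121 for the parental response, 470 to 2215 and 644 to 2039 for that of the HIF knockout and 45 to 221 and 1 to 34 for that of the ZMYND8 knockout. They were 713 to 2546 and 1249 to 3041, and 642 to 3184 and 951 to 3795 for the HIF knockout at 1% and 20% O2, 1035 to 2495 and 1342 to 3150, and 733 to 2279 and 1166 to 2944 for the ZMYND8 knockout, 20 to 769 and 82 to 885, and 18 to 391 and 44 to 419 for the differences, 1805 to 3299 and 1586 to 3416 between knockouts and 119 to 432 for the overlap. Libraries that moved a count by over 1.5 times included the 4 parental ones for each comparison with them; HIF knockout replicate 1 at 20% O2 for its own comparisons (2215 and 2039, 3184 and 3795, and 769 and 885) and both HIF knockout libraries at 20% O2 for the ZMYND8 knockout's response (221 or 220, and 34) and difference (389 and 418, or 391 and 419), the parental response (2121 or 2120 lower) and the overlap; both HIF knockout libraries at 1% O2 for its response and difference (43 and 155, or 30 and 147) and replicate 1 for its comparison with parental cells (968 higher); and the ZMYND8 knockout libraries for its comparisons (1084, 1430 and 1250 at 1% O2) and for the HIF knockout's difference (52 to 65 higher). HIF1A in the ZMYND8 knockout at 1% O2, 0.03 and not called, ranged from -0.0231 without ZMYND8 knockout replicate 1 to 0.0921 without its replicate 2, and was -0.00122 without parental replicate 1.

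With 0.5 reciprocal overlap HIF-1alpha regions met ZMYND8 in 49.2% and H3K14ac in 9.66%, ZMYND8 met H3K14ac in 4.80% and H3K14ac met ZMYND8 in 1.51%. Within 1 kb these were 86.9, 92.2, 90.3 and 46.7%, with ZMYND8 and H3 at 0.86%. For the higher-scoring 50% they were 64.7, 55.0, 45.5 and 17.0%, and for regions called in both samples 63.4, 62.8, 56.8 and 15.9%, with H3 at 11.7% of HIF-1alpha and 1.29% of ZMYND8 regions. Without H3 regions HIF-1alpha met H3K14ac in 55.1%. From regions of 1 library the ranges were 63.6 to 81.4, 58.1 to 59.2, 55.9 to 58.9 and 14.2 to 23.3%, with H3 at 7.90 to 10.6% and 0.643 to 1.32%. Odds ratios for ZMYND8 regions turned to below 1 for raised genes that the HIF knockout lowered (0.68 at 1 kb, 0.91 at 50 kb, 0.96 for the higher-scoring 50%), for those that the ZMYND8 knockout lowered (0.87 at 1 kb, but 1.24 at 50 kb and 1.36 in both samples, past the threshold) and for those that the HIF knockout did not lower (0.97 at 1 kb). Within the 422 genes the ZMYND8 odds ratio was above 1 at 50 kb (1.036), 0.90 at 1 kb, 0.76 for the higher-scoring 50%, 0.77 for both samples and 0.57 stratified by expression, and that of HIF-1alpha 0.62 at 50 kb. From regions of 1 library the ranges were 6.38 to 8.52, 2.78 to 3.72, 1.74 to 2.02, 0.292 to 0.377 and 0.637 to 0.699 for HIF-1alpha, and 1.11 to 1.15, 1.06 to 1.32, 1.16 to 1.63, 0.661 to 0.750 and 0.573 to 0.784 for ZMYND8.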

Other observations

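The counts of genes silent or lower in both knockouts and the overlaps by oxygen level were chosen only after the data were seen. At both oxygen levels 593 genes were lower and 208 higher in both knockouts than in parental cells. At 20% O2 1092 genes were lower in both (336 by independent calls) and 584 higher (189), and at 1% O2 949 (403) and 513 (249), where the shared parental libraries add to each overlap. The covariance across genes of the 2 knockouts' changes was 0.105 at 1% and 0.152 at 20% O2. Simulated unchanged groups with shared controls gave means of 0.0189 and 0.0188, and a correlation of 0.50 at each level from the sharing alone. The observed correlations, 0.33 and 0.54, thus cannot judge likeness. The 3 segments hold 3.69% of the tested genes and 120 of the 1092 genes lower in both at 20% O2.

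A set of 8 genes was below 1 in every knockout library and at 5 or more in every parental library, where independent silencing, equally likely for every gene, would give 0.0342 (18 genes in the HIF knockout and 20 in the ZMYND8 knockout of 10514). They were the aldolase ALDOC (6.34 ± 1.11 in parental cells at 20% O2), KRBOX1 in the chromosome 3 segment (9.44 ± 0.915), the lipoprotein receptor LSR (5.82 ± 0.318), the calcium channel subunits CACNA2D4 (5.24 ± 0.324) and CACNG7 (6.85 ± 0.893), the laminin LAMA4 (6.75 ± 0.0769), ZNF415 (6.60 ± 0.344) and the teneurin TENM2 (5.39 ± 0.0104). All 8 lay at 5.24 to 9.44 in parental cells at 20% O2, near the cut of 5. Genes this low fall below 1 more readily than most, so 0.0342 is too low as a level for them. In the other direction 0 genes were switched on in both knockouts, 1 in the HIF knockout and 10 in the ZMYND8 knockout. The 8 genes fell outside the rule for named genes where not already named and were chosen after their values were seen.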
